A study of Homo sapiens with 18 samples.

How the data were processed

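RNA levels were measured with 18 Agilent 1-colour microarrays. Of these, 6 arrays held HCT116, a human colorectal carcinoma line with a stable near-diploid karyotype, and 12 held RPE-1, a telomerase-immortalised human retinal pigment epithelium line. Per the labels' protocols, cells were grown without treatment in DMEM with 10% FBS, synthetic control transcripts were added to the total RNA, less of which was used for RPE-1 than for HCT116, and Cy3 was incorporated with the Quick-Amp kit (HCT116) or its low-input form (RPE-1). The array designs differ: 014850, annotated on hg18, for HCT116 and 028004, annotated on hg19, for RPE-1. For that reason the cell lines were fitted separately, except for the chromosome 5 difference between them. That difference came from 1 fit of all arrays over the probes that both designs share.

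The deposited values are spot intensities, per the file headers: Agilent Feature Extraction subtracted the local background, detrended each array and wrote a processed intensity that was not normalised between arrays. The headers name version 10.5.1.1 for HCT116 and 10.7.3.1 for RPE-1, where the submitters' processing notes name 10.5.1. Each array is 1 sample, with no dye partner and no pooling. The files hold 41000 probes on 43376 spots (HCT116) and 42405 probes on 58717 spots (RPE-1), control spots not counted among the probes. Between 69.2% and 77% of the HCT116 spots and between 61.1% and 63.5% of the RPE-1 spots were well above background by the image software's own call, and no spot was saturated. The 75th percentile of the processed intensity lay between 741 and 1628 in HCT116 and between 633 and 777 in RPE-1. The number of arrays, 3 per group, limits the precision.

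Spots that the image software marked as non-uniform or as population outliers were left out. Processed intensities were taken as log2, each array's 75th percentile over non-control probes was subtracted, and spots of the same probe were averaged. A probe was kept when it was well above background on all 3 arrays of at least 1 group. A probe with a missing value on any array of the fit was dropped. For a gene with several kept probes, the probe with the highest mean was used. Probes were named through the transcript accessions, symbols and older symbols that the files give, matched to a RefSeq gene table of assembly GRCh38.p14, which served for names and for the chromosome of genes without an hg19 probe position. In this way 18178 genes were named on the HCT116 design and 20529 on the RPE-1 design, while 14190 and 13898 probes stayed unnamed and were left out. The older design gives no gene symbols: 17708 of its probes took the name of the identically named RPE-1 probe and 9102 were named by accession. Coordinates are those of the hg19 probes.

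Group differences were estimated with limma 3.58.1 in R 4.3.3 (with version 1.17.8 of data.table) with empirical Bayes moderation, and adjusted by Benjamini and Hochberg over all genes of the fit. A gene counts as changed at an adjusted p under 0.05 with no fold limit. Fold changes are aneuploid over diploid on the log2 scale, ± the standard error of the fit, n = 3 arrays per group. The series describes 3 biological replicates per group, but no label says whether these were separate cultures, so the p-values measure the spread between arrays only. Where a gene was at background on all arrays of a group, its fold is given as a lower bound, computed after raising that group's values to the lowest intensity well above background on each array. Where part of the arrays of a group was above background, their number is given and the size of the fold is not exact. The shift of a chromosome is the median log2 fold change of its genes minus the median over the chromosomes without a stated gain, and it was tested with camera (competitive gene set test, preset correlation 0.01, and again with the estimated correlation) and by exact two-sided permutation of the 6 arrays, for which 0.1 is the smallest possible p. Windows held 20 neighbouring genes. Differences between the aneuploid RPE-1 lines were tested as an interaction in the fit of all 12 arrays.

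Before the data were examined, 27 gene lists were fixed: DNA replication, mitosis, ribosomal proteins, ribosome biogenesis, spliceosome, lysosome, autophagy, endocytosis and vesicle trafficking, MHC class I antigen presentation, interferon-stimulated genes, inflammatory cytokines and NF-kB targets, p53 targets, the unfolded protein response, the ATF4 and amino acid response, heat shock and cytosolic chaperones, proteasome subunits, glycolysis, mitochondrial oxidative phosphorylation, cholesterol synthesis, NRF2 and oxidative stress, the hypoxia response, extracellular matrix, histones, and markers of colon and simple epithelium, of retinal pigment epithelium and mesenchyme, of blood and endothelium, and of neural cells. A list needed 5 measured members and a chromosome 20. List tests used camera over the 27 lists with both correlations, and fry for direction. A list is called at an adjusted p under 0.05 with the preset correlation. The genes named in the text follow a rule fixed at the same time: per aneuploid line, the 8 largest rises and 8 largest falls among changed genes whose 3 arrays lay all above or all below those of the other group, the 3 largest rises and falls on each gained chromosome, up to 4 changed members of each called list, and SQSTM1, MAP1LC3B, LAMP1, LAMP2, MCM2 to MCM7, CDKN1A, HSPA1A and B2M in every case. Not every gene that meets this rule is printed. For the comparison of diploid lines and for the interaction, 5 rises and 5 falls were taken, and 8 of each by mean change for genes changed in all 3 aneuploid lines.

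The design, the lists, the naming rule and the alternatives were chosen before the data were examined. The alternatives were quantile normalisation, spike-in scaling, scaling outside chromosomes 5, 12 and 21, normexp background correction with an offset of 50 (on the median spot signal for HCT116, whose files lack the mean signal), no filter or a filter on all arrays, the mean over probes, a variance trend, the replicate number or the slide as a block, a 2-fold limit, only the arrays compared, both RPE-1 diploid groups as the control, the estimated correlation, lists without members on gained chromosomes, and leaving out each array in turn. Fits within each slide, with the other RPE-1 diploid group as the control and with a probe GC trend removed were added after seeing the data, as were runs of 60 neighbouring genes along chromosome 5.

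The array labels share replicate numbers. Same-numbered arrays of HCT116 correlated in their deviations from the group means at 0.26, -0.45 and 0.46 and those of RPE-1 at 0.018 or less, so the numbers do not pair the arrays and the main fits hold no replicate block. The slide codes in the headers put the arrays of each cell line on 2 slides, with HCT116 diploid replicates 1 and 2 on a slide of their own, so that the slide block compares diploid replicate 3 with the 3 aneuploid arrays. The RPE-1 groups were spread over both slides. Slide as a block or within-slide values stand beside part of the results, and within a slide 1 of the groups compared has a single array. No pair of arrays shared more than 0.0017% of identical spot values.

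The computations were tested on simulated data made from the real means and residual spreads, with 200 genes changed, 50 per fold size. The noise was drawn independently for each gene, so the test says nothing about list calls under correlation between genes. It was made after the gene tests had first been run on the real arrays. For HCT116 4x Chr5 against HCT116 diploid, 0% of 1.5-fold, 8% of 2-fold, 48% of 4-fold and 80% of 8-fold changes were recovered among 14673 genes, with 2 false calls. For RPE-1 3x Chr5 3x Chr12 the shares were 72%, 90%, 96% and 100% among 14258 genes, with 8 false calls. For RPE-1 H2B-GFP 3x Chr21 they were 82%, 88%, 100% and 100%, with 12 false calls. For H2B-GFP diploid against diploid RPE-1 they were 76%, 92%, 100% and 98%, with 7 false calls. The 4-fold and 8-fold sizes were added when the smaller ones were not recovered in HCT116. A chromosome shift of 0.5 was recovered as 0.496 to 0.502 in the 4 comparisons. Gene names and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.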

Results

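RNA levels were measured on 18 arrays in 6 groups of 3. The HCT116 groups were diploid and with 4 copies of chromosome 5 (4x Chr5). The RPE-1 groups were the parental diploid line, a line with 3 copies of chromosomes 5 and 12 (3x Chr5 3x Chr12), a diploid line that carries a fusion of histone H2B with GFP (H2B-GFP diploid), and an H2B-GFP line with 3 copies of chromosome 21 (3x Chr21). Each aneuploid karyotype was measured in a single line, so effects of a gain cannot be told apart from other differences between the lines. Between 69.2% and 77% of HCT116 spots and between 61.1% and 63.5% of RPE-1 spots were well above background. Arrays of the same group correlated at 0.971 to 0.992 in HCT116 diploid, 0.957 to 0.997 in HCT116 4x Chr5 and 0.996 to 0.998 in the RPE-1 groups. The HCT116 groups were less separate: 4x Chr5 replicate 1 correlated with the diploid arrays at 0.956 to 0.957 and with replicates 2 and 3 at 0.960 and 0.957. With 4x Chr5 replicates 2 and 3, diploid replicate 3 correlated at 0.954 and 0.951, and diploid replicates 1 and 2 at 0.916 to 0.925. H2BC11, a histone H2B gene, lay higher by 7.19 ± 0.05 (log2, SE) in H2B-GFP diploid than in parental RPE-1, the group whose label names no fusion.

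The comparison of HCT116 4x Chr5 with HCT116 diploid asked which genes change on the gained chromosome and which elsewhere. On chromosome 5, BASP1, a membrane-bound signalling protein of growth cones, rose by 10.84 ± 0.26 (log2, SE, n = 3, limma adjusted p = 8.91e-06), a size set in part by background because 1 of the 3 diploid arrays was above it. NNT, the mitochondrial transhydrogenase that supplies NADPH, was at least 58.0-fold higher. SQSTM1, a chromosome 5 gene whose product carries ubiquitinated cargo into autophagosomes, rose by 2.05 ± 0.21 (adjusted p = 0.0037; 2.19 with slide as a block). Among genes of other chromosomes, the nuclear receptor corepressor NRIP1 was at least 309-fold lower and the stem cell surface protein PROM1 at least 74.7-fold lower. Interferon-stimulated genes had a median log2 fold change of 1.73 over 40 genes (1.59 with slide as a block), and the antiviral sensor OAS1 was at least 26.4-fold higher, a call lost with slide as a block.

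Chromosome 5 genes lay above the other chromosomes by a median of 0.74 (1.67-fold, 671 genes). Over the 3 aneuploid arrays the shift was 0.73 ± 0.06 (SD), from 0.66 to 0.79, while the diploid arrays lay between -0.00 and 0.01. The diploid values are taken against their own mean, which holds them near 0. Against the mean of all HCT116 arrays, the diploid arrays lay between -0.397 and -0.353 and the aneuploid arrays between 0.231 and 0.395. The exact permutation p was 0.1, the smallest that 3 against 3 allows. Camera gave p = 8.39e-17, or 8.55e-04 with an estimated correlation. This shift was 74.1% of the log2 increase in copy number, and it was 0.71 with slide as a block. Of these genes 198 were higher, 7 were lower and 466 were not called. The 198 became 48 with slide as a block, 8 with normexp correction and 53 on the spike-in scale, and 48 to 325 when 1 array was left out. FYB1, an adaptor of immune cell signalling, rose by 8.14 ± 0.47 with 2 of the 3 diploid arrays above background. The zinc finger gene ZNF879 was at least 48.9-fold higher. Against this direction, the telomerase subunit TERT changed by -3.68, the actin-binding gene ENC1 by -2.98 and the protease ADAM19 by -2.79, and TERT and ADAM19 were not called with slide as a block, at -3.91 and -3.54. Medians of 20 neighbouring genes were above 0 in 28 of 33 windows, from -0.16 at 57749993 to 64961838 (hg19) to 1.67 at 41730471 to 50689665.

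Over the genome, 1012 of 14673 genes changed, 651 higher and 361 lower, and 807 of them lay outside chromosome 5. Of the tested genes 29.7% had groups that did not overlap, where chance gives 10%. The protease inhibitor A2M was at least 208-fold higher, the acute-phase protein SAA1 at least 86.4-fold higher and the potassium channel KCNH8 at least 54.6-fold higher. Falls were seen in the phosphodiesterase PDE4B (-8.62 ± 1.17, 2 of 3 aneuploid arrays above background), the protocadherin PCDH7 (-8.32 ± 0.26, 1 of 3), the matrix peroxidase PXDN (-8.18 ± 0.34, 1 of 3) and the growth factor BMP7 (-6.43 ± 0.23). KLHDC9 was at least 25.7-fold lower and the guidance factor SEMA3A at least 38.0-fold lower. With slide as a block, where the contrast rests on diploid replicate 3 alone because slide 1 holds no aneuploid array, 185 genes changed, 172 of them shared with the 1012, and all 1012 kept their sign, though A2M (adjusted p = 0.0993), PDE4B and KLHDC9 were then not called, with folds of similar size. Within the slide that holds 1 diploid and all 3 aneuploid arrays 27 genes changed. The count lay between 178 and 4155 when 1 array was left out (178 without diploid replicate 1, 263 without diploid replicate 2, 2280 without diploid replicate 3, 4155 without 4x Chr5 replicate 1, 220 without replicate 2 and 214 without replicate 3). Scaled to the spike-in transcripts, the median of all genes moved by -0.9985 and 164 genes were higher and 1185 lower. This move comes from diploid replicates 1 and 2 on slide 1, whose spike-ins lay 1.87 and 2.53 above the 75th percentile, against 3.84 in diploid replicate 3 and 3.61 to 3.87 in the aneuploid arrays on slide 2. The 75th percentile itself was 1628 and 1186 on these 2 arrays, against 741 to 855 on slide 2. Weaker spike-ins and brighter sample signal are therefore not told apart, and slide 1 holds diploid arrays only. With normexp background correction the median of all genes moved by -0.20 and 12 genes were higher and 16 lower.

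Of the 27 gene lists, 17 were called with the preset correlation, and 0 with the correlation that camera estimated (2 at an unadjusted p under 0.05). The calls of mitosis, ribosome biogenesis, ATF4, heat shock and extracellular matrix genes were lost with slide as a block. Of the 43 called list members considered for naming, SQSTM1 and NQO1 kept their call with the block, and the others kept their sign but not their call. Other settings also ended calls: spliceosome genes within slide 2 (median -0.30), inflammatory genes there (0.27) and with normexp correction, lysosome genes on the spike-in scale, and p53 targets without diploid replicate 3. Heat shock genes were not called in 8 of 18 settings. Interferon-stimulated genes stood highest, with 16 of 40 genes higher (30 adjusted over the list alone; adjusted p = 0.618 with an estimated correlation). Among them were IFI44 (5.66, 1 of 3 diploid arrays above background), IFIT3 (4.28, 2 of 3) and the RNA sensor IFIH1 (3.94). In MHC class I antigen presentation, with a median of 1.12 (1.01 with slide as a block), 7 of 22 genes were higher (16 adjusted over the list alone; adjusted p = 0.618 with an estimated correlation). The immunoproteasome subunit PSMB9 rose by 2.43, the transcription factor IRF1 by 2.46, the MHC light chain B2M by 1.61 and the peptide transporter TAP1 by 1.55. NRF2 genes had a median of 0.52 (0.68), with rises of the reductases AKR1C3 (5.21), AKR1C1 (4.74) and NQO1 (2.12). In this list 7 of 28 were higher and 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.313). Hypoxia genes stood at 1.101 (0.56) with 4 of 20 higher (6 and 1 lower adjusted over the list alone; 0.618). NDRG1 rose by 2.48, ANKRD37 by 2.05 and the prolyl hydroxylase P4HA2 by 1.78. Of the genes named here, IRF1 and P4HA2 lie on the gained chromosome, as does SQSTM1.

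Autophagy genes had a median of 0.47 (0.44 with slide as a block) and lysosome genes 0.29 (0.26). The autophagy receptor OPTN rose by 1.94, the conjugating enzyme ATG3 by 1.29 and GABARAPL2 by 0.95. Of the list 4 of 42 autophagy genes were higher and 1 lower (12 and 1 adjusted over the list alone; adjusted p = 0.618 with an estimated correlation). The proton pump subunit ATP6V0E1 rose by 1.75, the protease CTSD by 1.34 and GM2A by 1.30. Of the list 5 of 62 lysosome genes were higher and 2 lower, and as many adjusted over the list alone (0.313). MAP1LC3B, the membrane marker of autophagosomes, stood at 1.06 (adjusted p = 0.0704), LAMP1 at 0.45 (0.194) and LAMP2 at 0.80 (0.107), and none of these was called. Inflammatory and NF-kB genes stood at 0.82 (0.52), with 4 of 24 higher (9 and 2 lower adjusted over the list alone; 0.618). BIRC3 rose by 3.44, NFKB2 by 0.91. The cytokines CSF2 and CCL5 were at least 3.37-fold and 3.48-fold higher, with -0.25 and -0.17 under normexp correction. p53 targets stood at 0.31 (0.42; 4 of 36 higher and 1 lower, 6 and 2 adjusted over the list alone; 0.618). There TNFRSF6B rose by 2.58, CDKN1A, the inhibitor of cyclin-dependent kinases, by 2.07, FAS by 1.55 and PHLDA3 by 1.23. Extracellular matrix genes stood at 0.61 (0.10; 7 of 36 higher, 13 and 1 lower adjusted over the list alone; 0.649). The laminin LAMA4 was at least 10.4-fold higher, and FBN2 rose by 3.92 with 2 of 3 diploid arrays above background. ATF4 genes stood at 0.82 (0.34; 0 of 33 called by limma, 12 at an unadjusted p under 0.05; 0.676). Unfolded protein response genes stood at 0.49 (0.24; 2 of 33 higher, and 2 over the list alone; 0.649), where the chaperone CANX rose by 1.30 and WFS1 by 0.85. Of the genes named here, ATP6V0E1, GM2A, CSF2, FBN2 and CANX lie on the gained chromosome.

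The lists below the other genes were mitosis (-1.01, and -0.53 with slide as a block, where it was not called at adjusted p = 0.0973; over all alternatives 1.69e-13 to 0.168), DNA replication (-0.91, -0.69), cholesterol synthesis (-0.81, -1.07), ribosome biogenesis (-0.61, -0.31), spliceosome (-0.44, -0.30) and heat shock and chaperones (-0.41, 0.02). Their adjusted p with an estimated correlation were 0.704, 0.649, 0.618, 0.649, 0.676 and 0.854. Of the cholesterol genes 6 of 25 were lower (14 lower and 1 higher adjusted over the list alone): INSIG1 changed by -1.71 and MVK by -1.58. In the mitosis, replication, biogenesis and spliceosome lists limma called 0 genes, with 7, 18, 16 and 12 at an unadjusted p under 0.05. MCM2 to MCM7, the subunits of the replicative helicase, lay between -0.82 and -1.71 without a call. The heat shock list had 1 gene higher and 1 lower of 42. HSPA1A stood at -0.82 (adjusted p = 0.438; 0.35 with slide as a block), and the cochaperone CHORDC1 changed by -1.76. Replicate 1 of 4x Chr5 stood apart from replicates 2 and 3. Mitosis genes lay at 0.36, -1.59 and -1.59 on the 3 arrays, replication genes at -0.03, -1.41 and -1.44, ATF4 genes at 0.11, 1.32 and 1.23, and interferon-stimulated genes at 0.85, 2.28 and 2.25. On the spike-in scale only interferon-stimulated (0.73), MHC class I (0.12) and hypoxia genes (0.10) kept a median above 0 among the lists called higher. That scale is displaced by the 2 diploid arrays on slide 1, whose spike-ins were low relative to their sample signal. The lists not called were ribosomal proteins (-0.01), endocytosis (0.19), proteasome (-0.19), glycolysis (median 0.01, mean -0.11), oxidative phosphorylation (-0.13), histones (-0.34), and the colon (-0.08), retinal pigment epithelium (median 0.07, mean -0.01), blood (median -0.10, mean 0.16) and neural (0.11) markers.

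**Figure D1:**
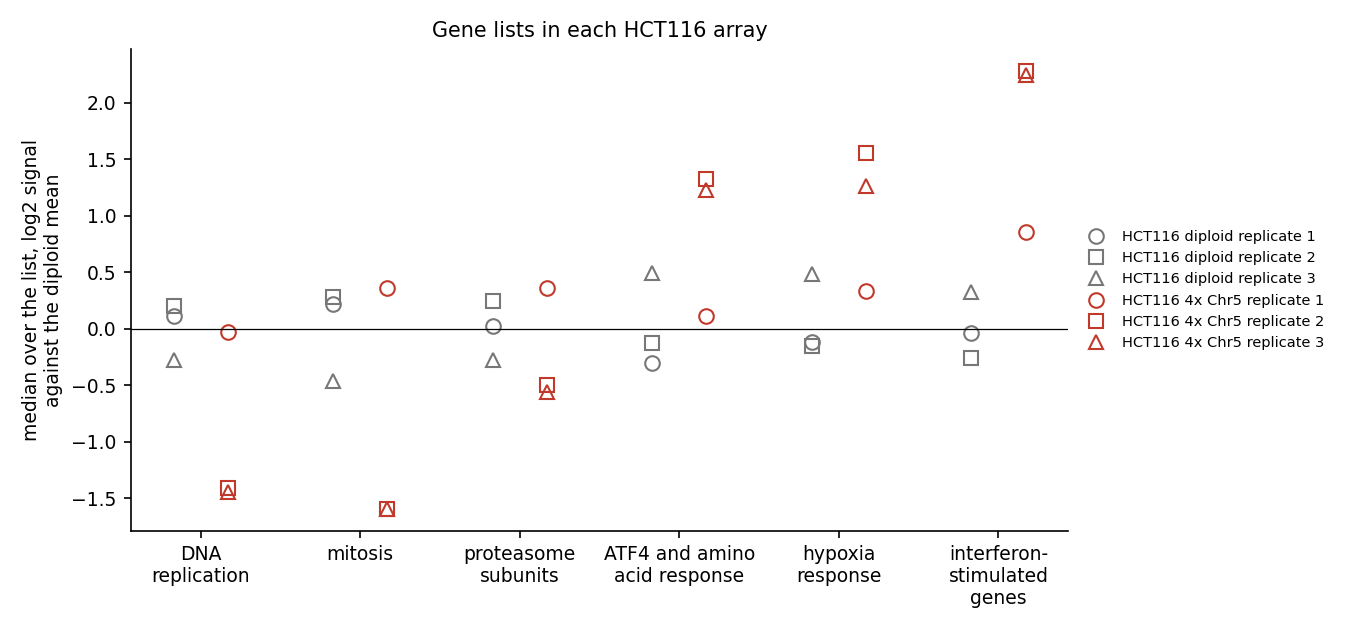
Median log2 difference of gene lists on each HCT116 array from the mean of the diploid arrays, 1 point per array. Mitosis genes lay at 0.36 on replicate 1 of 4x Chr5 and at -1.59 on replicates 2 and 3, and interferon-stimulated genes lay above 0 on all 3.

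The comparison of RPE-1 3x Chr5 3x Chr12 with diploid RPE-1 asked the same question for a gain of 1 copy of each of 2 chromosomes. HOXB6, a homeobox gene of anterior-posterior patterning, was at least 527-fold higher and its neighbour HOXB5 at least 125-fold higher, and both lie on chromosome 17. HOXB6 was also higher in H2B-GFP diploid than in parental RPE-1, by 7.35, an inexact size because the parental arrays were at background. On chromosome 5, SQSTM1 rose by 0.74 ± 0.05 (log2, SE, n = 3, limma adjusted p = 9.99e-07; 0.75 with slide as a block). CDKN1A rose by 1.02 ± 0.04 (adjusted p = 1.31e-08) and MDM2, the ubiquitin ligase of p53 encoded on the gained chromosome 12, by 1.31 ± 0.05. Ribosomal protein genes had a median of 0.28 over 77 genes (0.31 and 0.29 within the 2 slides), with 75 higher, as many adjusted over the list alone. The median was 0.06 with quantile normalisation and 0.19 against H2B-GFP diploid, and the call was kept in both, though not with an estimated correlation.

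Chromosome 5 genes lay above the other chromosomes by 0.51 (1.43-fold, 654 genes) and chromosome 12 genes by 0.52 (1.43-fold, 737 genes). Per array the means were 0.51 ± 0.01 and 0.52 ± 0.01 (SD, n = 3, exact permutation p = 0.1 each), and camera with an estimated correlation gave p = 3.86e-05 and 4.79e-06. These shifts were 87.3% and 88.3% of the log2 increase in copy number, and 0.50 and 0.51 with slide as a block. On chromosome 5, 481 genes were higher and 51 lower, and on chromosome 12, 569 and 47. The homeobox gene IRX2 was at least 109-fold higher, the matrix link protein HAPLN1 at least 70.2-fold higher and FLJ32255 at least 35.8-fold higher on chromosome 5. There the protocadherin PCDHA6 was at least 8.66-fold lower, PCDHA11 changed by -2.01 (2 of 3 aneuploid arrays above background) and the methyltransferase BHMT2 by -1.51. On chromosome 12 the calcification inhibitor MGP was at least 61.4-fold higher, ARHGDIB rose by 4.91 and CD163L1 was at least 23.2-fold higher. The neurotrophin NTF3 was at least 96.8-fold lower, the channel KCNJ8 at least 16.5-fold lower and PIANP changed by -2.50. All 32 windows of chromosome 5 and all 36 of chromosome 12 had medians above 0.

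**Figure D2:**
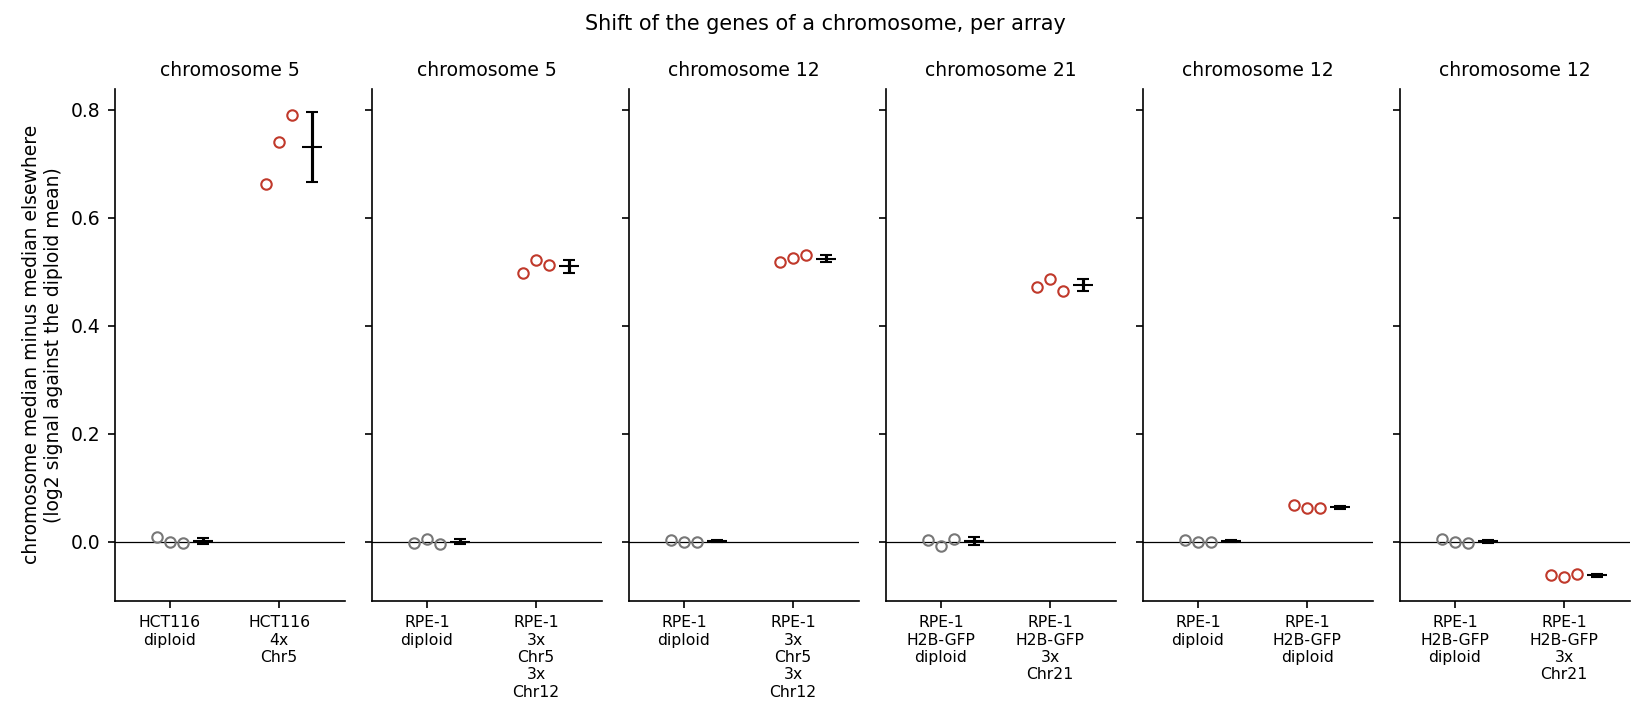
Median log2 difference of the genes on a chromosome from the other chromosomes, 1 point per array, against the mean of the diploid control arrays. Gained chromosomes are shown, and also chromosome 12 in H2B-GFP diploid and in 3x Chr21, where no gain of it is stated. The HCT116 4x Chr5 arrays lay between 0.66 and 0.79 and the RPE-1 3x Chr5 3x Chr12 arrays between 0.50 and 0.52 on chromosome 5.

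Over the genome, 8552 of 14258 genes changed, 4191 higher and 4361 lower, with 579 and 497 of them by at least 2-fold. The balance depended on the scaling: 3507 were higher and 5036 lower with quantile normalisation, 4993 and 3607 when scaled outside chromosomes 5, 12 and 21, and 2828 and 3597 on the spike-in scale. With slide as a block 8455 changed, and within the 2 slides 5168 and 5344, where 1 of the groups has a single array. Groups did not overlap in 66.6% of genes (10% by chance). PLXNA4, a semaphorin receptor, rose by 7.72 ± 0.26, SLAMF7, a receptor of immune cells, by 7.12 ± 0.35 (1 of 3 diploid arrays above background), and HOXB9 was at least 106-fold higher. SLAMF7 and HOXB9 were also higher in H2B-GFP diploid than in parental RPE-1, by 6.91 and 6.66, so these rises are not particular to the gain. Parental arrays at background make these sizes inexact. Falls outside chromosomes 5 and 12 included MAGED4B at least 116.2-fold, FUOM, a fucose mutarotase, at least 37.9-fold, MGARP at least 31.6-fold and the growth factor CLEC11A at least 22.3-fold, with SERP2 at -5.64 and CGREF1 at -5.34 (1 of 3 aneuploid arrays above background).

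Of the 27 lists 12 were called, and 0 with the correlation that camera estimated (2 at an unadjusted p under 0.05). Against H2B-GFP diploid the calls of ATF4, interferon, hypoxia and DNA replication genes were lost, the last also on the spike-in scale. Endocytosis genes were not called in 8 and heat shock genes not in 9 of 22 settings. ATF4 and amino acid genes had the highest median, 0.81 (29 of 33 higher and 1 lower, and as many adjusted over the list alone; 0.91 and 0.74 within slides; adjusted p = 0.357 with an estimated correlation). It included ASNS, the asparagine synthetase, at 2.13, the cystine carrier SLC7A11 at 1.64, PSAT1 at 1.49 and CTH at 1.38. Set against the H2B-GFP diploid arrays in place of the parental ones, the list median was 0.06, ASNS stood at -0.28, PSAT1 at -0.00 and CTH at -0.30. p53 targets stood at 0.62 (0.55 and 0.62 within slides; 27 of 35 higher and 1 lower, 28 and 1 adjusted over the list alone; adjusted p = 0.0829) and at 0.40 against H2B-GFP diploid. They included CYFIP2 at 1.47, the tetraspanin CD82 at 1.40 and the cytokine GDF15 at 1.26. MHC class I genes stood at 0.45 (0.38 and 0.47; 19 of 23 higher and as many over the list alone; 0.143) and at 0.25 against H2B-GFP diploid. ERAP2, which trims peptides, rose by 1.22, TAP2 by 1.01, IRF1 by 0.75, PSMB9 by 0.71 and B2M by 0.45. Interferon-stimulated genes stood at 0.41 (0.30 and 0.45; 24 of 41 higher and 7 lower, and as many over the list alone; 0.448) and at 0.07 against H2B-GFP diploid. There SAMD9 was at least 8.59-fold, OASL at least 2.71-fold and BST2 at least 2.65-fold higher, and OAS2 rose by 3.09. CYFIP2, ERAP2 and IRF1 lie on chromosome 5 and OASL and OAS2 on chromosome 12, which have an extra copy here. Without members on chromosomes 5, 12 and 21 the medians were 0.58 for p53 targets, 0.33 for MHC class I and 0.38 for interferon-stimulated genes.

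Ribosomal proteins (adjusted p = 0.357 with an estimated correlation) included RPS14 at 0.80, RPL37 at 0.78, RPL27A at 0.75 and RPS23 at 0.71. DNA replication genes stood at -0.13 (-0.12 and -0.14 within slides; 7 of 50 higher and 27 lower, 7 and 28 adjusted over the list alone; 0.357). Among them were ORC2 at -0.76, the polymerase subunit POLE2 at -0.71, DNA2 at -0.56, and MCM2 to MCM7 between -0.15 and -0.53. Oxidative phosphorylation stood at 0.14 (46 of 75 higher and 2 lower, 46 and 3 over the list alone; 0.357) with NDUFS4 at 0.89, NDUFA9 at 0.78, ATP5F1B at 0.77 and NDUFS6 at 0.77. Proteasome subunits stood at 0.13 (20 of 42 higher and 1 lower, and as many over the list alone; 0.513) with PSMD9 at 0.69, PSMD12 at 0.41, PSMB7 at 0.39 and PSMA7 at 0.33. With quantile normalisation both calls were lost, at medians of -0.0029 and 0.0025. RPS14, RPL37, RPS23, NDUFS4 and NDUFS6 lie on chromosome 5, and NDUFA9, ATP5F1B and PSMD9 on chromosome 12, which have an extra copy here. Without members on chromosomes 5, 12 and 21 the medians were 0.27 for ribosomal proteins, 0.12 for oxidative phosphorylation and 0.13 for proteasome subunits. The calls of hypoxia (0.29, 13 of 20 higher and 3 lower, 13 and 4 over the list alone; 0.357), heat shock (0.18, 25 of 43 and 7, as many over the list alone; 0.514), ribosome biogenesis (0.13, 30 of 56 and 6, 31 and 7 over the list alone; 0.448) and endocytosis genes (0.07, 27 of 62 and 7, 26 and 6 over the list alone; 0.357) were not kept without their members on chromosomes 5 and 12 (adjusted p = 0.0836, 0.35, 0.084 and 0.334). The medians were then 0.25, 0.09, 0.11 and 0.04, so that with fewer genes those of hypoxia and ribosome biogenesis stayed close to their size. In these lists LOX, a collagen crosslinker, rose by 1.58, CA9 by 1.16, STC2 by 1.04, NDRG1 by 0.85, HSPB8 by 1.04, HSPA9 by 0.90, CCT2 by 0.64, and HSPA6 by 0.62. EMG1 rose by 0.82, RIOK2 by 0.69, NOP16 by 0.66, NOP2 by 0.66, CLTB by 0.82, EHD4 by 0.77, VPS33A by 0.76 and RAB5B by 0.74. Of the members named for these lists, all except CA9, NDRG1, HSPA6 and EHD4 lie on chromosome 5 or 12. LAMP1 rose by 0.12 (-0.09 with quantile normalisation) and LAMP2 by 0.28, HSPA1A changed by -0.51, and MAP1LC3B stood at -0.01 (adjusted p = 0.873). Mitosis genes (median -0.01, mean 0.04) and colon markers (-0.05, 0.17) were not called.

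**Figure D3:**
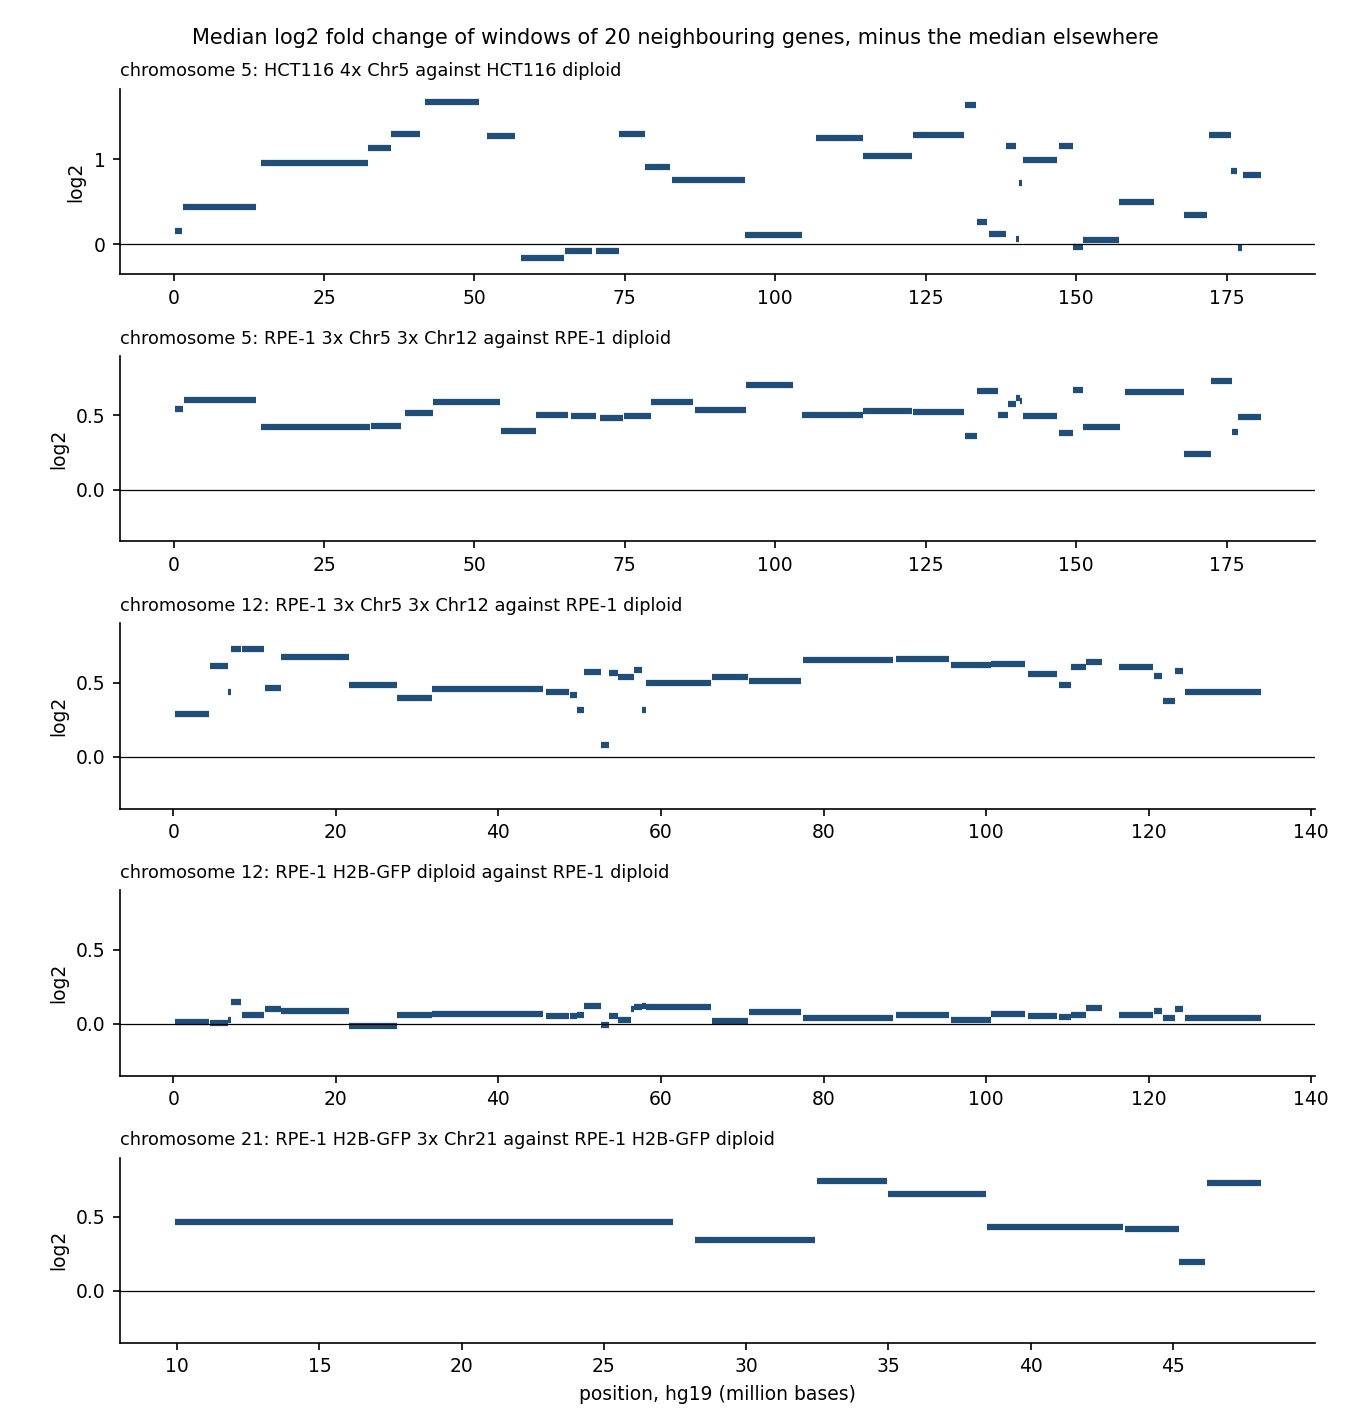
Median log2 fold change of 20 neighbouring genes minus the median elsewhere, by hg19 position, 1 bar per window. In RPE-1 all windows of the gained chromosomes lay above 0, and in HCT116 28 of 33 windows of chromosome 5 did.

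The comparison of RPE-1 H2B-GFP 3x Chr21 with H2B-GFP diploid asked which genes differ in a line that gained the small chromosome 21. COL6A2, a collagen VI chain encoded on chromosome 21, was at least 155-fold higher, and its neighbour COL6A1 rose by 4.96 ± 0.04 (log2, SE, n = 3, limma adjusted p = 8.65e-13). The surface protein CD109, a binder of TGF-beta, was at least 333-fold lower and TMEM98 at least 252.5-fold lower. Histone genes had a median of -0.57 over 45 genes (-0.61 and -0.55 within the 2 slides), with 37 lower and 4 higher, and H2BC6 changed by -1.93 ± 0.09. LGMN, a lysosomal endopeptidase, rose by 1.32 ± 0.07.

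Chromosome 21 genes lay above the other chromosomes by 0.48 (1.39-fold, 164 genes; 0.47 ± 0.01 per array, SD, n = 3, exact permutation p = 0.1; camera p = 3.74e-04 with an estimated correlation). That was 81.9% of the log2 increase in copy number, and 0.50 with slide as a block, and all 8 windows were above 0. Of these genes 106 were higher and 16 lower. LRRC3 was at least 41.4-fold higher and the kinase RIPK4 rose by 4.34, whereas TCP10L changed by -1.24, TEKT4P2 by -0.84 and KRTAP19-7 by -0.59.

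Over the genome 9337 of 14258 genes changed, 4577 higher and 4760 lower, with 549 and 562 by at least 2-fold. With slide as a block 9291 changed, and 6081 within slide 1, with 1 diploid array. Groups did not overlap in 69.7% of genes (10% by chance). Scaled to the spike-in transcripts, the median of all genes moved by -0.18, and 2380 genes were higher and 5848 lower. The carrier SLC22A15 was at least 34.1-fold, the endothelial proteoglycan ESM1 at least 47.2-fold, the sulfatase SULF1 at least 17.7-fold and the dynein chain DYNC1I1 at least 11.6-fold higher. Against parental RPE-1, SULF1 stood at -0.84. PTGFRN was at least 50.5-fold, the matrix proteoglycan FMOD at least 21.97-fold and the GTPase RHOD at least 20.4-fold lower. GSTM3, a glutathione transferase, changed by -6.27, MAGEH1 by -5.80 (2 of 3 aneuploid arrays above background) and BCHE by -5.26 (1 of 3).

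Of the 27 lists 13 were called, and 0 with the correlation that camera estimated (3 at an unadjusted p under 0.05). Histones (37 lower and 4 higher adjusted over the list alone; adjusted p = 0.285 with an estimated correlation) included H2BC7 at -1.39, H4C11 at -1.15 and H2AC16 at -1.12. DNA replication genes stood at -0.32 (-0.32 and -0.26 within slides; 6 of 50 higher and 36 lower, and as many over the list alone; 0.285). MCM10 changed by -0.86, MCM2 by -0.78, PRIM1 by -0.68 and MCM7 by -0.65, and MCM3 to MCM6 lay between -0.38 and -0.59. Mitosis genes stood at -0.29 (-0.27 and -0.26; 4 of 38 and 27, as many over the list alone; 0.285), with the kinesin KIF20A at -0.81, the transcription factor FOXM1 at -0.81, SPC24 at -0.61 and BUB1B at -0.60. Spliceosome genes stood at -0.19 (10 of 59 and 38, as many over the list alone; 0.285) with SF3B3 at -0.78, SNRNP40 at -0.64, LSM4 at -0.61 and SRSF7 at -0.56. Ribosomal proteins stood at -0.10 (5 of 77 and 34, 5 and 32 over the list alone; 0.802) with RPSA at -0.39, RPS3 at -0.33, RPLP0 at -0.32 and RPL28 at -0.30. This call was lost against parental RPE-1 (-0.0069), against both diploid groups and within slide 2.

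Lysosome genes stood at 0.24 (0.25 and 0.27 within slides; 42 of 61 higher and 9 lower, 42 and 10 over the list alone; adjusted p = 0.285 with an estimated correlation). They included the proteases CTSL at 1.19 and CTSZ at 1.19 and GM2A at 1.06. CTSZ stood at -0.67 against parental RPE-1. LAMP1 rose by 0.33, LAMP2 by 0.20 and MAP1LC3B by 0.33, and SQSTM1 stood at -0.07 (adjusted p = 0.293). Autophagy genes (0.16, 22 of 42 and 9, 23 and 9 over the list alone; 0.335) included GABARAPL1 at 1.32, WIPI1 at 1.01, TP53INP2 at 0.97 and ATG4A at 0.74. Endocytosis genes (0.16, 35 of 62 and 6, as many over the list alone; 0.285) included CLTB at 0.98, CAV2 at 0.77 and EHD1 at 0.65, with medians of 0.00 and -0.00 on the spike-in scale. Unfolded protein response genes stood at 0.26 (0.28 and 0.30; 26 of 34 and 3, as many over the list alone; 0.330), where the chaperones DNAJB9, DNAJC3 and HSPA5 rose by 1.17, 1.00 and 0.75 and SELENOS by 0.88. Cholesterol genes stood at 0.34 (0.32 and 0.38; 17 of 24 and 2, as many over the list alone; 0.330) with HMGCS1 at 1.35, IDI1 at 1.18 and NSDHL at 0.93. Against parental RPE-1 the cholesterol median was 0.15 and the call was lost. Hypoxia genes stood at 0.34 (0.32 and 0.38; 12 of 20 and 3, 13 and 3 over the list alone; 0.285) with ANGPTL4 at 3.53, LOX at 1.82, NDRG1 at 1.69 and P4HA2 at 1.37. p53 targets stood at 0.28 (21 of 35 and 9, as many over the list alone; 0.330) with FAS at 1.08, PERP at 0.95, DDB2 at 0.92, SPATA18 at 0.85 and CDKN1A at 0.60. The p53 call was lost within slide 1, with fewer arrays and a median of 0.28, and with normexp correction at 0.24. Extracellular matrix genes stood at 0.24 (24 of 44 and 10, as many over the list alone; 0.490), with MFAP5 at 3.88, and without COL6A1 and the other members on chromosome 21 the list missed the threshold at adjusted p = 0.0517 (0.00138 to 0.0579 over all alternatives), as it did against parental RPE-1. MHC class I genes were not called and had a median of 0.16 but a mean of -0.17. B2M rose by 0.42 and HSPA1A changed by -0.39. Heat shock genes (median -0.07, mean 0.01) and blood markers (-0.04, 0.26) were not called either.

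**Figure D4:**
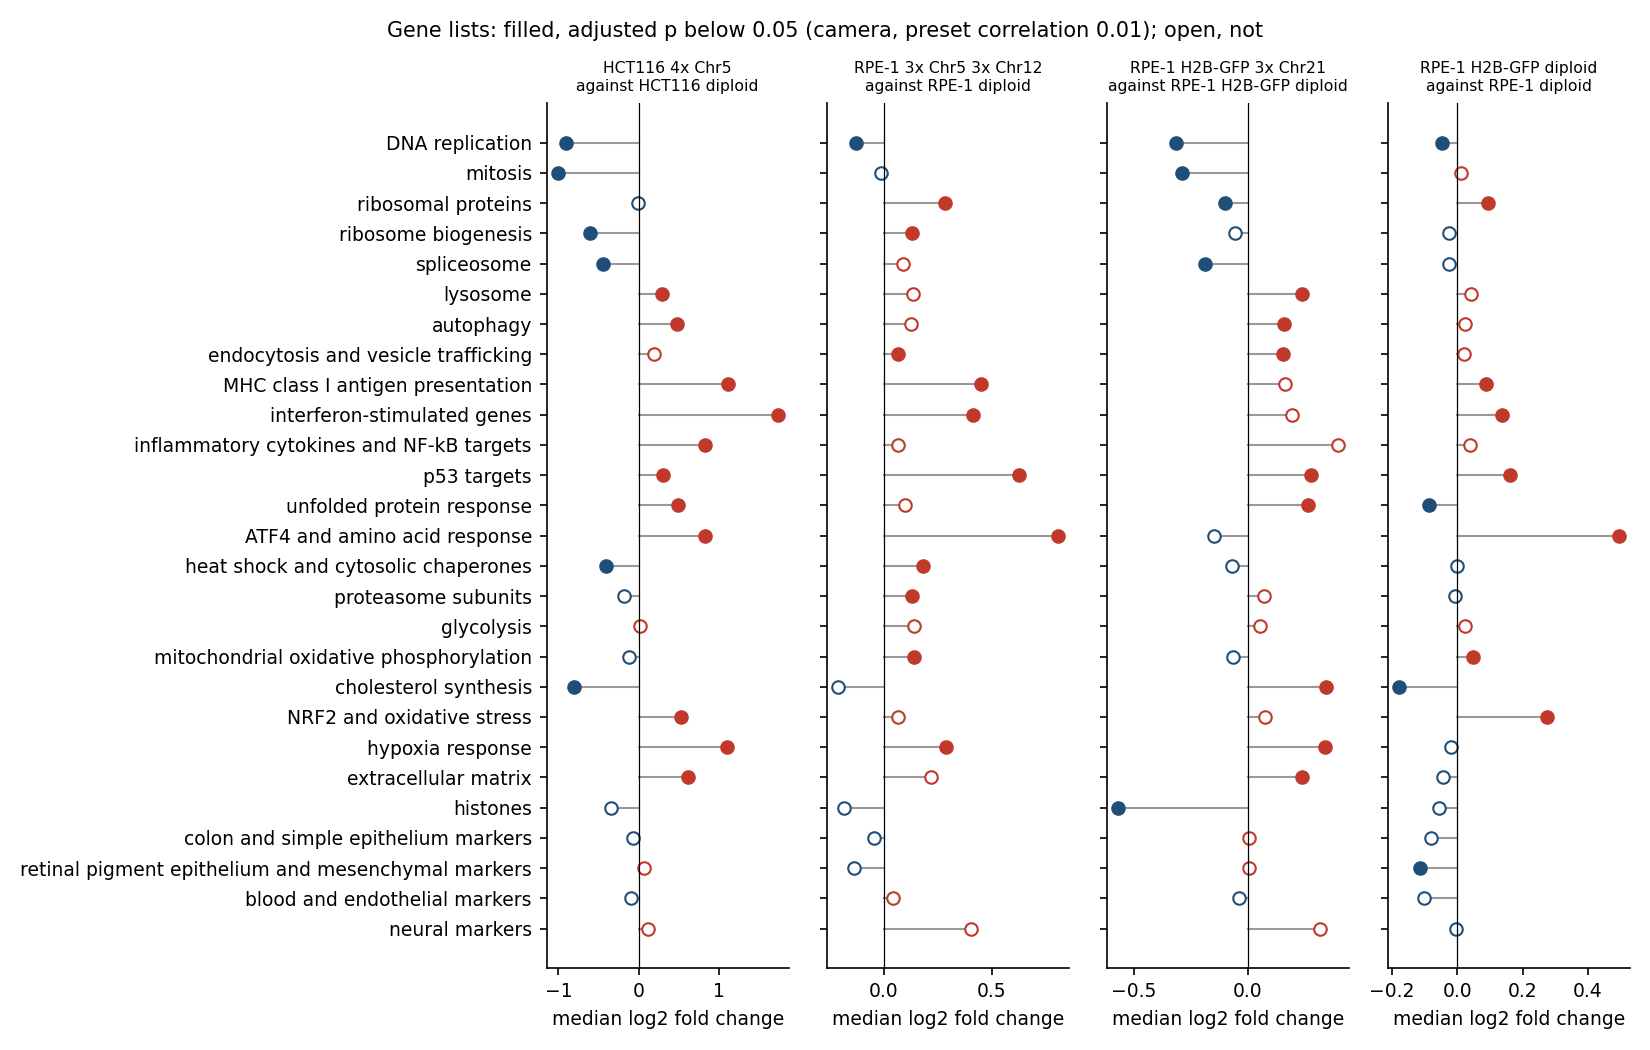
Median log2 fold change of each gene list in the 4 comparisons, filled where called with the preset correlation. Interferon-stimulated genes reached 1.73 in HCT116 4x Chr5, and histones reached -0.57 in 3x Chr21.

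The comparison of H2B-GFP diploid with parental RPE-1 gives the difference between lines without a stated gain. HOXB6 was at least 163.5-fold and HOXB9 at least 89.2-fold higher, and the glutamate carrier SLC1A1 at least 47.7-fold higher. ASNS rose by 2.41 ± 0.04 (log2, SE, n = 3, limma adjusted p = 1.99e-11), and ATF4 genes had a median of 0.49 over 33 genes (0.51 and 0.47 within the 2 slides). AKR1C1, a reductase induced by NRF2, was at least 15.5-fold higher.

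In all, 2192 of 14258 genes changed, 1167 higher and 1025 lower, with 175 and 77 by at least 2-fold. With slide as a block 2017 changed, and within slides, each with 1 array of 1 group, 223 and 377, and groups did not overlap in 36.6% of genes (10% by chance). On the spike-in scale 608 were higher and 332 lower, and with quantile normalisation 1092 and 1241. SLAMF7 rose by 6.91 (1 of 3 parental arrays above background). SULF1 was at least 31.8-fold, the adhesion protein FLRT2 at least 4.70-fold, ZNF793 at least 6.29-fold and QNG1 at least 7.67-fold lower, and the inflammasome adaptor PYCARD changed by -3.02 (2 of 3 H2B-GFP arrays above background). Chromosome 12 genes lay above the others by 0.06 (0.06 to 0.07 over the 3 arrays, 737 genes, 108 higher and 27 lower, camera p = 2.59e-05), and over all chromosomes the adjusted p was 0.0569 with an estimated correlation.

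Of the 27 lists 11 were called, of which NRF2 genes (0.27; 0.23 and 0.29 within slides; 18 of 27 higher and 1 lower, 20 and 1 adjusted over the list alone) kept the call with an estimated correlation (adjusted p = 0.032). They included AKR1C3 at 3.68, SLC7A11 at 0.99 and AKR1B10 at 0.72. ATF4 genes (26 of 33 higher, 29 over the list alone; 0.0614 with an estimated correlation) included CHAC1 at 2.58, CTH at 1.68 and PSAT1 at 1.49. p53 targets stood at 0.16 (15 of 35 higher, 19 and 1 lower over the list alone; 0.0614) with SESN2 at 0.97, BBC3 at 0.74, CYFIP2 at 0.67 and BTG2 at 0.65. Interferon-stimulated genes stood at 0.14 (13 of 41 higher, as many over the list alone; 0.238) with GBP2 at 1.55 (2 of 3 parental arrays above background), SAMD9L at 1.17, IFI44L at 0.99 and BST2 at least 1.44-fold. Ribosomal proteins (0.09, 17 of 77 higher, 20 over the list alone; 0.538) included RPL27A at 0.36, RPL22 at 0.25 and RPSA at 0.20. MHC class I genes (0.09, 8 of 23, 10 over the list alone; 0.238) included HLA-B at 0.41, PSMB9 at 0.38, HLA-F at 0.38 and TAP2 at 0.28. In oxidative phosphorylation (0.05, 3 of 75, and 0 over the list alone by limma with 11 at an unadjusted p under 0.05; 0.767) were NDUFA11 at 0.17, COX7C at 0.15 and CYC1 at 0.11. Cholesterol genes stood at -0.18 (13 of 24 lower, 16 over the list alone; 0.137) with SC5D at -0.54, TM7SF2 at -0.45, SREBF2 at -0.31 and MVD at -0.29. Retinal pigment epithelium and mesenchymal markers stood at -0.11 (6 of 21 lower, 8 over the list alone; 0.137) with PDGFRA at -0.89, PDGFRB at -0.61, OTX2 at -0.38 and ACTA2 at -0.23. Unfolded protein response genes stood at -0.09 (2 of 34 higher and 6 lower, 2 and 8 over the list alone; 0.734) with CREB3L2 at -0.23, MANF at -0.22, DNAJC3 at -0.20 and HSPA5 at -0.18. DNA replication genes stood at -0.05 (1 of 50 higher and 8 lower, 1 and 9 over the list alone; 0.238) with POLE2 at -0.28, MCM2 at -0.26, ORC1 at -0.25 and GINS3 at -0.24. Oxidative phosphorylation was not called in 4 of 19 settings, and the unfolded protein response not on the spike-in scale and without H2B-GFP diploid replicate 2. RPSA, CYC1 and DNAJC3 were not called with slide as a block, at 0.20, 0.12 and -0.20. Median and mean differed in sign for the uncalled lists of lysosome (0.04, -0.01), glycolysis (0.02, -0.01), hypoxia (-0.02, 0.07), histone (-0.06, 0.57) and neural genes (-0.00, 0.16).

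Whether different gains change the same genes was asked over the 12530 genes tested in all 3 aneuploid lines, whose comparisons share no array. SH2D1B, an adaptor of natural killer cells, rose by 6.31 (log2) in HCT116 4x Chr5, with 1 of 3 diploid arrays above background, and was at least 9.94-fold higher in RPE-1 3x Chr5 3x Chr12 and 7.775-fold in 3x Chr21. AKR1C1 rose by 4.74 in HCT116 4x Chr5 and 2.48 in 3x Chr21 and was at least 7.58-fold higher in 3x Chr5 3x Chr12. PCDH7 changed by -8.32 in HCT116 4x Chr5, -0.34 in 3x Chr5 3x Chr12 and -0.70 in 3x Chr21. In total 181 genes were higher in all 3, against 51.9 for independent lists, and 61 were lower, against 30.8. Without chromosomes 5, 12 and 21 these were 92 (26.0) and 60 (30.8). The expected numbers take all 3 lists as independent, but the RPE-1 lines shared 1480 higher (897.1) and 1976 lower genes (1293) with each other. HCT116 4x Chr5 shared 139 higher (80.2) and 130 lower genes (90.3) with 3x Chr5 3x Chr12, and 160 higher (105.2) and 93 lower genes (90.7) with 3x Chr21, so part of the excess comes from sharing between the RPE-1 lines. The total of 242 was 36 with slide as a block and 7 with normexp correction, and leaving out 1 array gave 36 to 879. Also higher in all 3 were MGP, BASP1, DCLK1, MIA and STRA6, and lower were KLHDC9, BEX4, TSPAN2, APOC1, ZNF585B, CPT1C and KLHL35. The HCT116 call was lost with slide as a block for MGP (2.65), STRA6 (3.25), KLHDC9 (-6.58), APOC1 (-2.40) and ZNF585B (-4.50), whose folds stayed about as large, and for AKR1C1 (3.42) and DCLK1 (3.67 from 5.32). Across genes, which are not independent replicates, fold changes of HCT116 4x Chr5 correlated at r = 0.114 (rank correlation 0.0719) with RPE-1 3x Chr5 3x Chr12 and at 0.112 (0.149) with 3x Chr21, and those of the RPE-1 lines at 0.307 (0.345).

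The RPE-1 gains were compared with each other by the interaction, and the gains of chromosome 5 between the cell lines. Each against its own diploid line, PTGFRN was at least 25.6-fold higher in 3x Chr5 3x Chr12 and at least 50.5-fold lower in 3x Chr21. EPHB6, a kinase-inactive ephrin receptor, stood at 3.44 in 3x Chr5 3x Chr12 and was at least 30.5-fold lower in 3x Chr21. Both genes were also higher in H2B-GFP diploid than in parental RPE-1, PTGFRN by 6.49 (parental arrays at background) and EPHB6 by 2.90. In all, 8163 of 14258 genes differed (4055 and 4988 within slides), 6988 of them outside chromosomes 5, 12 and 21 and 1363 by at least 2-fold. On chromosome 5, 489 genes measured by the same probes had a shift of 0.75 in HCT116 and 0.52 in RPE-1, a difference of 0.23 (camera over n = 489 genes, p = 0.0314; 0.23 with slide as a block, p = 0.0291). Of these, 168 genes were counted as larger and 113 as smaller in HCT116, and the others as neither. The p-values and counts come from a fit of both cell lines with 1 residual variance per gene. In the separate fits the median residual SD was 0.35 in HCT116 and 0.075 in RPE-1, so the shared variance can understate the error of HCT116. With normexp correction the difference was 0.075. Over 24 alternatives it lay between 0.075 and 0.33, with a camera p (n = 489 genes in the main setting) between 0.00281 and 0.105.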

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

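The tests by other splits of the arrays and by probe GC content were set down before their results were seen. The tests of a wrong label, slide, dim array and growth state, of a few genes and a partial gain of chromosome 12, and of the parental line were chosen after the patterns were seen.

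The genes, lists and chromosome of this paragraph and the next 2 are set out because a test of the difference between the RPE-1 gains, or between cell lines, passed its threshold. The effects of the RPE-1 gains differed for 8163 genes. PTGFRN, an inhibitor of prostaglandin receptor binding, differed by 12.03, HOXB6 by 9.97, HOXB9 by 8.89, EPHB6 by 8.38 and SLAMF7 by 8.37, each higher in 3x Chr5 3x Chr12. NTF3 differed by -9.39, MAGED4B by -8.12, COL6A2 by -7.44, SULF1 by -6.79 and ARRDC4 by -6.75. All of these except SLAMF7 rest on a group with 0 arrays above background, so they are no exact folds. With the same diploid group as the control of both lines, the differences were 5.54, 2.62, 2.23, 5.48, 1.46, -8.52, -7.91, -7.43, -1.34 and -5.58 in the same order. For HOXB6, HOXB9, SLAMF7 and SULF1 all arrays of both aneuploid groups were above background, so their same-control differences are measured values. They were smaller than the differences between the diploid lines, 7.35, 6.66, 6.91 and -5.45, so most of the interaction of these genes came from the diploid lines. For the others an aneuploid group had arrays at background, and the shares cannot be read. In 100 drawn splits within each pair of lines, 2 gave as many genes, the real one included, and the highest other gave 9629. That split keeps all groups whole and exchanges diploid and aneuploid arrays in 1 pair of lines, so that it adds the effects where the real one subtracts them, and the next highest gave 4376.

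Lists without members on gained chromosomes differed between the RPE-1 gains as well. ATF4 genes lay higher in 3x Chr5 3x Chr12 by 0.60, interferon-stimulated genes by 0.47, ribosomal proteins by 0.35, histones by 0.32, MHC class I genes by 0.23, oxidative phosphorylation by 0.22, spliceosome genes by 0.21, mitosis genes by 0.15 and ribosome biogenesis by 0.14. Cholesterol genes differed by -0.59, retinal pigment epithelium and mesenchymal markers by -0.26, unfolded protein response genes by -0.20, lysosome genes by -0.17 and endocytosis genes by -0.16. The adjusted p lay between 1.09e-12 for ribosomal proteins and 0.0412 for the retinal markers (camera, preset correlation), and an estimated correlation was not run for the difference. For histones, spliceosome, ribosome biogenesis, lysosome and endocytosis genes, H2B-GFP diploid over parental lay at -0.06, -0.02, -0.03, 0.04 and 0.02. These are opposite in sign to the differences above, while the other lists had the same sign. By medians over all list members, part of the ATF4 and interferon differences comes from the diploid lines. Over parental RPE-1, ATF4 genes stood at 0.81 in 3x Chr5 3x Chr12 and 0.38 in 3x Chr21, and over H2B-GFP diploid at 0.06 and -0.15. Interferon-stimulated genes stood at 0.41 and 0.45 over parental RPE-1 and at 0.07 and 0.19 over H2B-GFP diploid. These medians over all 41 members were not higher in 3x Chr5 3x Chr12 with the same control. The 0.47 above is a median of differences per gene over 35 members, so it is not the gap between such medians. A difference per gene with the same control was not computed for lists.

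Chromosome 5 rose by 0.23 more in HCT116 with 4 copies than in RPE-1 with 3. In 100 drawn splits 54 gave a difference as large (highest other 1.28), so this test does not argue against chance. A split that breaks up or exchanges the gain in 1 line alone gives a large difference by its construction, and whether 0.23 exceeds what other arrays would give stays open.

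For the gene counts, 10 splits of 6 arrays are too few for a share under 0.05. In HCT116 4x Chr5, 1 split gave as many genes (1012, highest other 871), 7 as many shifted chromosomes (1, highest other 2), 2 as many lists (17, highest other 18) and 1 as many higher genes on chromosome 5 (198, highest other 12). The split with 871 genes puts 4x Chr5 replicate 1 with diploid replicates 1 and 2, and that with 18 lists puts diploid replicate 1 with 4x Chr5 replicates 2 and 3. In 3x Chr5 3x Chr12 the numbers were 1 for genes (8552, highest other 1), 10 for chromosomes (2, highest other 2), 2 for lists (12, highest other 13), and 1 each for higher genes on chromosomes 5 (481, highest other 0) and 12 (569, highest other 0). For 3x Chr21 they were 1 for genes (9337, highest other 0), 10 for chromosomes (1, highest other 1), 2 for lists (13, highest other 13) and 1 for chromosome 21 (106, highest other 0), and for H2B-GFP diploid 1 for genes (2192, highest other 0), 1 for chromosomes (1, highest other 0) and 2 for lists (11, highest other 12). Every other split leaves more aneuploid arrays on 1 side, so part of a gain remains and camera can still call its chromosome. The chromosome counts of the aneuploid lines therefore do not test chance. For genes changed alike in all 3 aneuploid lines, 1 of 100 drawn combinations gave as many (242, highest other 0). Other splits of the RPE-1 arrays called 0 or at most 1 gene, so they leave almost nothing to overlap by construction. This test therefore cannot decide whether the lines share genes.

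Replicate 1 of HCT116 4x Chr5 lacked the lower mitosis and replication genes of replicates 2 and 3. A diploid array under the wrong label is argued against by its chromosome 5 shift of 0.66, and a slide effect by the 3 arrays of the group sharing 1 slide. Its 75.3% of spots well above background lay within the range of the other 5 arrays but below the 76.4% to 77% of the others on its slide, and its median signal was the lowest of the 6, so a dim array is argued against only weakly. Its mitosis median lay 1.95 above the mean of the other 2 arrays, and a different growth state of the culture may account for this. No label records culture density or harvest, so that stays open, as does a difference between isolates.

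Chromosome 12 lay above the other chromosomes by 0.06 in H2B-GFP diploid RPE-1. Of its genes 69.1% lay above 0 (52.1% on the highest other chromosome), which restates the shift of the median and is no separate test of a few genes. A slide effect is argued against by at least 0.060 within each slide, and probe GC content by a shift of 0.062 once its trend was removed. An extra chromosome 12 in part of the cells is a candidate explanation that stays open. Over windows, H2B-GFP diploid minus 3x Chr21 was set against the full gain in 3x Chr5 3x Chr12, as these contrasts share no array. The rank correlation was -0.58, opposite to the prediction of a partial gain. On the other chromosomes with at least 10 windows it lay between -0.485 and 0.327, with a median of -0.259. A negative value is therefore not particular to chromosome 12. A gain of this size would move windows by an SD of 0.015, where those of H2B-GFP diploid minus 3x Chr21 spread by 0.139. The test therefore cannot decide, and this condition was added after the value was seen. The 3x Chr21 line, which also carries H2B-GFP, lay at 0.01 against parental RPE-1.

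The higher ATF4 genes of 3x Chr5 3x Chr12 were seen against parental RPE-1, not against H2B-GFP diploid, where the median was 0.064. That value is the observation that prompted the pattern, so it does not test whether the parental group stands apart. H2B-GFP diploid lay above parental by 0.49, and by at least 0.47 within a slide, which argues against a slide effect. A difference between the lines or between cultures could give this value and the design does not separate them.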

How the results depend on the processing

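The fits within slides and with the other RPE-1 diploid group were chosen after seeing the data, as was the rule that counts a list as reversed only where it was called under at least 1 of the settings. Of 485 values of the main results under alternatives, 435 kept their direction and side of the threshold (counts within 1.5 times), 47 moved, 3 were weaker and 0 reversed. Of 5619 values of named genes, 5010 kept theirs, 568 were weaker, 17 stronger and 24 reversed, and of 2291 values of lists 2117 kept theirs, 111 were weaker, 57 stronger and 6 reversed. Where nothing else is said, the cause was not tested. The shifts of the gained chromosomes kept their direction and call throughout.

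With normexp background correction, HCT116 4x Chr5 had 28 changed genes (8 higher on chromosome 5), 7 genes changed alike in all 3 lines, and the chromosome 5 difference was 0.075, no longer under the p threshold. CSF2 stood at -0.25 and CCL5 at -0.17 in HCT116, MAP1LC3B at 0.0077 in 3x Chr5 3x Chr12, and in HCT116 the ribosomal list at 0.20 and oxidative phosphorylation at 0.057. With quantile normalisation LAMP1 stood at -0.094 in 3x Chr5 3x Chr12. On the spike-in scale 940 genes changed in H2B-GFP diploid and 53 were higher on chromosome 5 in HCT116, where LAMP1 stood at -0.55, LAMP2 at -0.20, WFS1 at -0.15, NFKB2 at -0.091, GABARAPL2 at -0.050 and INSIG2 at -0.0046. The HCT116 medians move by -0.9985 on that scale, which turns these signs by construction. The move rests on diploid replicates 1 and 2 on slide 1, whose spike-ins lay 1.87 and 2.53 above the 75th percentile, against 3.61 to 3.87 on slide 2. Whether spike-ins or sample signal differ there is not told apart. MAP1LC3B in 3x Chr5 3x Chr12 stood at 0.045 when scaled outside chromosomes 5, 12 and 21, and at 0.19 as the mean of probes. Restricted to probes well above background on all arrays, the chromosome 5 difference was 0.175, again over the p threshold.

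With slide as a block, which for HCT116 rests on diploid replicate 3 alone and so is nearly the fit within slide 2, HCT116 had 185 changed genes (48 higher on chromosome 5), 36 genes changed alike in all 3 lines, HSPA1A stood at 0.35 and heat shock genes at 0.018. Within slide 2, HCT116 had 27 changed genes (9 on chromosome 5) and 11 lists, with HSPA1A at 0.35 and heat shock genes at 0.018, and there were 5344 changed genes in 3x Chr5 3x Chr12, 377 in H2B-GFP diploid and 4988 whose RPE-1 effects differed, with SQSTM1 at 0.068 in 3x Chr21. Within slide 1 these counts were 5168, 223 and 4055, and 6081 in 3x Chr21. The fits within slides hold fewer arrays, with 1 array in 1 of the groups compared, and the cause of their lower counts was not tested.

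A limit of at least 2-fold, which removes genes by construction, left 1076, 1111 and 252 genes in 3x Chr5 3x Chr12, 3x Chr21 and H2B-GFP diploid, 78, 61 and 25 higher genes on chromosomes 5, 12 and 21, and 1363 differing effects. With the correlation that camera estimated 0, 0, 0 and 1 lists were called in HCT116, 3x Chr5 3x Chr12, 3x Chr21 and H2B-GFP diploid (2, 2, 3 and 5 at an unadjusted p under 0.05). Without chromosomes 5, 12 and 21, 152 genes changed alike in all 3 lines. SQSTM1 in 3x Chr21 stood at 0.059 against both diploid groups. Against the other diploid group NRF2 genes stood at -0.21, ASNS at -0.28, PSAT1 at -0.0031 and CTH at -0.30 in 3x Chr5 3x Chr12, and ATF4 genes at 0.38, SULF1 at -0.84, SQSTM1 at 0.19 and CTSZ at -0.67 in 3x Chr21.

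Leaving out each array in turn gave 178 to 4155 changed genes in HCT116, 48 to 325 higher genes on its chromosome 5, 36 to 879 genes changed alike in all 3 lines, and a chromosome 5 difference of 0.217 to 0.315. Without HCT116 diploid replicate 3 that difference was 0.2945 and over the p threshold. MAP1LC3B in 3x Chr5 3x Chr12 lay between -0.032 and 0.019, above 0 without replicate 2 of either group (0.0185 and 0.0189).

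With the replicate number as a block, 1319 genes changed in HCT116, 8485 in 3x Chr5 3x Chr12, 9253 in 3x Chr21 and 2007 in H2B-GFP diploid, 8067 effects differed, and 298 genes changed alike in all 3 lines. Lists called were 18, 12, 13 and 11. The block gave 213 higher genes on chromosome 5 in HCT116, 485 and 571 on chromosomes 5 and 12, 106 on chromosome 21 and kept the chromosome 5 difference under the p threshold. It left each of these counts within 1.5 times its main value. Same-numbered arrays did not all correlate best with each other.

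Signal over background limits the folds of genes at background in 1 group, which are lower bounds, and probes of 1 gene differed in sign for 9.09% of called genes with several probes in HCT116, 17.8% in 3x Chr5 3x Chr12, 21.7% in 3x Chr21 and 16.4% in H2B-GFP diploid.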

Other observations

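The runs of neighbouring genes described here were chosen after the windows of chromosome 5 had been seen, and no explanation was tested. In HCT116 4x Chr5, the lowest run of 60 neighbouring genes on chromosome 5, from 56558753 to 73924314 (hg19), had a median of -0.16 against the other chromosomes (0.00 with slide as a block), where the rest of chromosome 5 had 0.84. In this run 25 of 60 genes lay above 0 and 1 was called higher. The aneuploid arrays gave -0.20, -0.20 and -0.13, and the diploid arrays -0.02, 0.03 and -0.04. The same genes had a median of 0.49 in RPE-1 3x Chr5 3x Chr12 (58 genes). No random order of the chromosome 5 genes had a run as low, a permutation p of 1e-04, the smallest that the number of orders allows, and the lowest run in these orders was -0.10. Random orders ignore any correlation between neighbouring genes.

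The highest run of 60 genes, from 32784961 to 52249308, had a median of 1.53 (1.31 with slide as a block), with 34 genes called higher, and 1.08, 1.51 and 1.51 on the aneuploid arrays. In RPE-1 3x Chr5 3x Chr12 its genes (47 measured) had a median of 0.45. On the 22 other chromosomes of HCT116, run medians lay between -0.66 and 0.39, with a range of at most 0.82 on 1 chromosome.

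AKR1C1 rose in all 3 aneuploid lines and also in H2B-GFP diploid over parental RPE-1, where it was at least 15.5-fold higher. Against parental RPE-1, NRF2 genes had a median of 0.50 in 3x Chr21, and against H2B-GFP diploid 0.07.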
